A study of Mus musculus with 27 samples.

How the data were processed

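The series measured polyadenylated RNA of primary naive B cells from the spleen of wild-type mice, uncultured or stimulated for 6 h or 24 h with anti-CD40 at 1 µg/mL (clone HM40-3), alone or with IL-4 at 12.5 ng/mL, IL-21 at 50 ng/mL or both. The 27 libraries form 9 groups of 3 by their labels: naive, and 4 stimulations at each of 2 times. Per the submitters' processing notes, reads were quantified with Salmon 1.9.0 on GRCm38/mm10. The deposited table holds values in TPM for 35604 genes, as the authors describe it, and no read counts. The listed values sum to 766384 to 825365 per library. TPM keeps no sequencing depth, so depth per library is unknown and the precision of low values cannot be derived from it. Of all genes, 10174 were 0 in every library. The between-library correlation of log2(TPM + 1) was 0.927 to 0.982 within groups and 0.823 to 0.972 between groups, and 0 pairs of libraries were identical.

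Gene IDs were matched to symbols, positions and types with GENCODE M21, which named 35254 of them. Genes with at least 1 TPM in at least 3 libraries were kept, which left 12147, of which 10583 were protein coding and 1277 pseudogenes. Values were used as listed, without rescaling, as log2(TPM + 1), a scale that understates changes of genes with low values. Of 3468 genes with a median of at least 20 TPM, 19 were listed at 0 in some library. Such values were kept, and for groups that hold them the libraries are given 1 by 1.

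A model with 1 mean per group was fitted to all 27 libraries with limma 3.58.1 in R 4.3.3, with moderated variances that follow a trend with the mean and 18 residual degrees of freedom. Comparisons were the effect of IL-21 with anti-CD40 and with anti-CD40 and IL-4, each at 6 h and 24 h, the interaction of IL-21 with IL-4 at each time, the change of each IL-21 effect from 6 h to 24 h, the effect of IL-4 with anti-CD40 and the effect of anti-CD40 against naive cells at each time. The last compared cultured with uncultured cells, so culture and stimulation could not be separated. P values were adjusted over all tested genes by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p below 0.05; the number changed at least 2-fold is given beside it. Comparisons, tests and main settings were chosen before the data were examined.

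Gene lists, 31 in number, of which 1 is not used here, were fixed from general knowledge before the values were examined: IL-21 and STAT3 response, IL-4 and STAT6 response, plasma cell program, mature B cell identity, germinal centre genes, immunoglobulin constant genes, pro-apoptotic BCL2 family and death receptors, anti-apoptotic genes, S phase and DNA replication, G2 and mitosis, cyclin-dependent kinase inhibitors, MYC targets and ribosome biogenesis, CD40 and NF-kB response, MHC class II and antigen presentation, T-bet and atypical B cell genes, trafficking receptors and regulators, cytokines and tumour necrosis factor ligands, glycolysis, cholesterol synthesis, endoplasmic reticulum stress and chaperones, SOCS and cytokine feedback, p53 targets, dissociation and heat stress genes, mitochondrially encoded genes, and markers of T cells, NK cells, macrophages and monocytes, neutrophils, dendritic cells, and erythroid cells and platelets. Each list was tested against all other genes with camera from limma at a preset correlation of 0.01 and again with an estimated correlation, with p adjusted over the lists of a comparison. Members were counted as called over all genes and when adjusted over the list alone. Genes changed at least 2-fold by IL-4 at one time were tested for the IL-21 effect at the other time, in libraries that had not served to choose them.

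Genes are named in the text by a rule. For each IL-21 effect these were the 6 largest rises and falls with a mean of at least 5 TPM in the higher group and no overlap between replicates; for the other comparisons the 4 largest, or 3 for the changes with time. To these were added a fixed panel, of which 1 gene is not used here (Prdm1, Bcl6, Irf4, Xbp1, Socs3, Il10, Myc, Il21r, Il4ra, Fcer2a and Pax5) and up to 3 called members of each list with any called member of opposite direction. Unnamed gene models, processed pseudogenes and single immunoglobulin segments were passed over.

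The libraries carry replicate numbers, and no label pairs them. After group means were removed, the correlation of libraries with the same number exceeded 0.1 for every pair in the comparisons of IL-21 with anti-CD40 at 6 h (0.186 to 0.335), IL-21 with anti-CD40 and IL-4 at 6 h (0.183 to 0.377) and IL-4 at 6 h (0.107 to 0.382), and in no other comparison. Across all libraries, 48 of 108 pairs exceeded 0.1, and 23 of 27 libraries correlated best with their own number. The number was therefore added as a block in 1 alternative.

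Alternatives planned beforehand were a pseudocount of 0.1, no filter, a filter at 5 TPM, median-of-ratios rescaling, no variance trend and the replicate block. Also planned were only the compared groups in the fit, IL-4-responsive genes chosen at adjusted p alone and an estimated correlation. Each library was to be left out in turn as well, for the comparisons that hold it. Alternatives added after seeing the data left out mitochondrial, ribosomal protein and pseudogene transcripts with the rest rescaled to a common sum, left out replicate 1 of the naive group and of the 24 h group with anti-CD40 and IL-4 for their low mitochondrial share while keeping 2 others low in it at 6 h, or left the 24 h group with anti-CD40 and IL-4 out of the fit. The procedure was tested on simulated data with 50 planted genes per size among 12147 genes run. For IL-21 with anti-CD40 at 6 h it recovered 4%, 26%, 92% and 100% of genes planted at 0.5, 1, 2 and 3 log2 units and called 4 genes without a planted change. For the interaction at 6 h it recovered 2%, 8%, 74% and 88% and called 5 such genes, and for the change with time without IL-4 0%, 12%, 70% and 96%, calling 2. In the comparisons of IL-21 with anti-CD40 and IL-4, where nothing was planted, 0 of 12147 genes were called. The simulated noise was independent, with the same spread of a gene in every library, and changes were planted only in genes with a mean above 2. Deviations from the group mean in the real 24 h libraries with anti-CD40 and IL-4 had SDs of 0.499, 0.265 and 0.422. The simulation therefore does not show the rate of false calls in comparisons with that group. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.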

Results

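Naive splenic B cells were compared before culture and after 6 h or 24 h with anti-CD40, alone or with IL-4, IL-21 or both cytokines, in 9 groups of 3 libraries. Changes are log2 differences ± standard error with n = 3 libraries per group, levels are mean ± SD in TPM, and 12147 genes were tested. Standard errors and p values rest on a spread per gene estimated from all 27 libraries, not from the compared groups alone. They can understate the uncertainty where a group varied more. Deviations from the group mean in the 24 h libraries with anti-CD40 and IL-4 had SDs of 0.499, 0.265 and 0.422. No label says whether the replicates came from separate animals or cultures, so each p measures the spread between these samples, which may be technical. Mitochondrially encoded transcripts made up 5.5% of replicate 1 of the naive group against 12.71% and 13.54% of replicates 2 and 3. They made up 7.89% of replicate 1 of the 24 h group with anti-CD40 and IL-4 against 11.63% and 10.97% of its other libraries, and ribosomal protein transcripts 21.33% against 26.85% and 27.32%. These are the 2 replicate 1 libraries that some counts below leave out. Lower mitochondrial shares than in the rest of their groups were also found at 6 h in replicate 3 with IL-4 (6.91% against 10.16% and 10.63%) and replicate 3 with IL-21 (7.27% against 10.91% and 10.23%), which those counts keep. The 24 h libraries with anti-CD40 and IL-4 serve in several comparisons, which are therefore not independent. They are the treated group of the IL-4 effect and the control of the IL-21 effect with IL-4. That IL-21 effect also enters the interaction at 24 h and the change with time with IL-4. Low values in these libraries lower the IL-4 effect and raise the others.

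**Figure D1:**
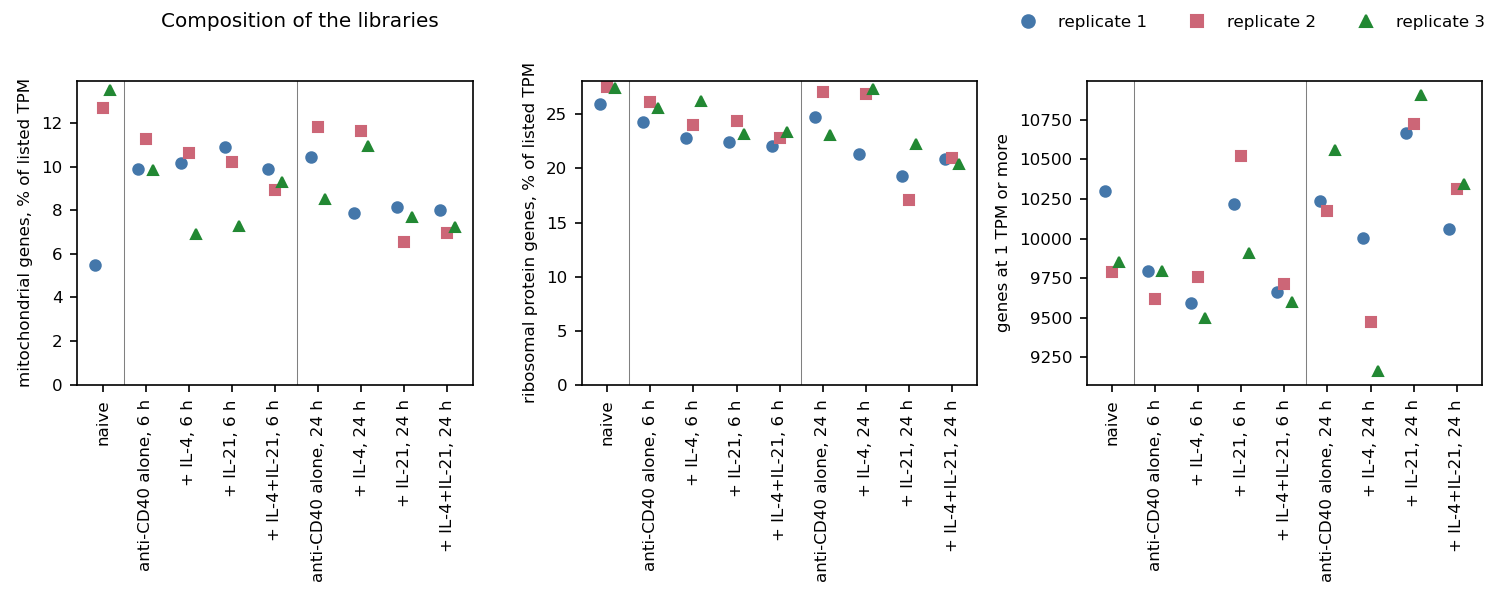
Share of mitochondrially encoded and ribosomal protein transcripts and number of genes at 1 TPM or more in each of the 27 libraries.

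IL-21 added to anti-CD40 for 6 h raised Socs3 (ENSMUSG00000053113, chr11:117966079-117970047), which encodes a suppressor of cytokine signalling. Its level went from 4.58 ± 0.786 to 387 ± 72.2 TPM (6.11 ± 0.27, adjusted p = 3.99e-13). Also raised were Muc1 (4.35 ± 0.30), the basic leucine zipper factor gene Nfil3 (3.93 ± 0.28) and the chromatin organiser gene Satb1, at 196 ± 29.8 against 14.5 ± 1.12 TPM (3.66 ± 0.30). Gem, for a small GTPase (3.64 ± 0.15), and Batf, for an AP-1 family factor that was at 312 ± 28.7 against 30.9 ± 2.72 TPM (3.29 ± 0.12), rose as well. The T-bet gene Tbx21 (2.77 ± 0.21), the cytokine gene Il10 (2.41 ± 0.20), from 0.506 ± 0.299 to 6.94 ± 0.855 TPM, and Bcl2l11, which encodes the pro-apoptotic protein BIM (1.77 ± 0.23), also rose. Among the genes that fell were Fcer2a (ENSMUSG00000005540, chr8:3681737-3694175), which encodes the low-affinity IgE receptor CD23, and Cd36. Fcer2a was at 26.2 ± 16 against 443 ± 281 TPM (-4.01 ± 0.58, adjusted p = 4.32e-05) and Cd36 at 1.29 against 20.9 TPM (-3.24 ± 0.40). The anti-apoptotic genes Bcl2a1b (-2.53 ± 0.23) and Bcl2l1 (-2.38 ± 0.31), the complement receptor gene Cr2 (-2.46 ± 0.31) and the CD20 gene Ms4a1 (-2.15 ± 0.19) fell as well. Prdm1, for the plasma cell factor Blimp-1, was at 1.29 ± 0.596 against 0.295 ± 0.325 TPM (0.82 ± 0.21, adjusted p = 0.0118), a call that ended when replicate 1 or 2 with anti-CD40 alone or replicate 3 with IL-21 was left out. The calls of Il21r (1.33 ± 0.36, adjusted p = 0.0152), Xbp1 (-1.24 ± 0.37, adjusted p = 0.0267) and Pax5 (-1.37 ± 0.38, adjusted p = 0.0178) likewise ended without single libraries. Bcl6 (-0.19 ± 0.25, adjusted p = 0.731), Irf4 (-0.32 ± 0.33, adjusted p = 0.622), Myc (0.63 ± 0.34, adjusted p = 0.281) and Il4ra (0.32 ± 0.45, adjusted p = 0.748) were not called. In all, 1471 genes were called, 903 higher and 568 lower, and 817 of them changed at least 2-fold. The count was 939 without replicate 1 of anti-CD40 alone and 974 without replicate 2 with IL-21. It was 2256 without the 2 replicate 1 libraries and 3212 with no filter on low values.

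**Figure D2:**
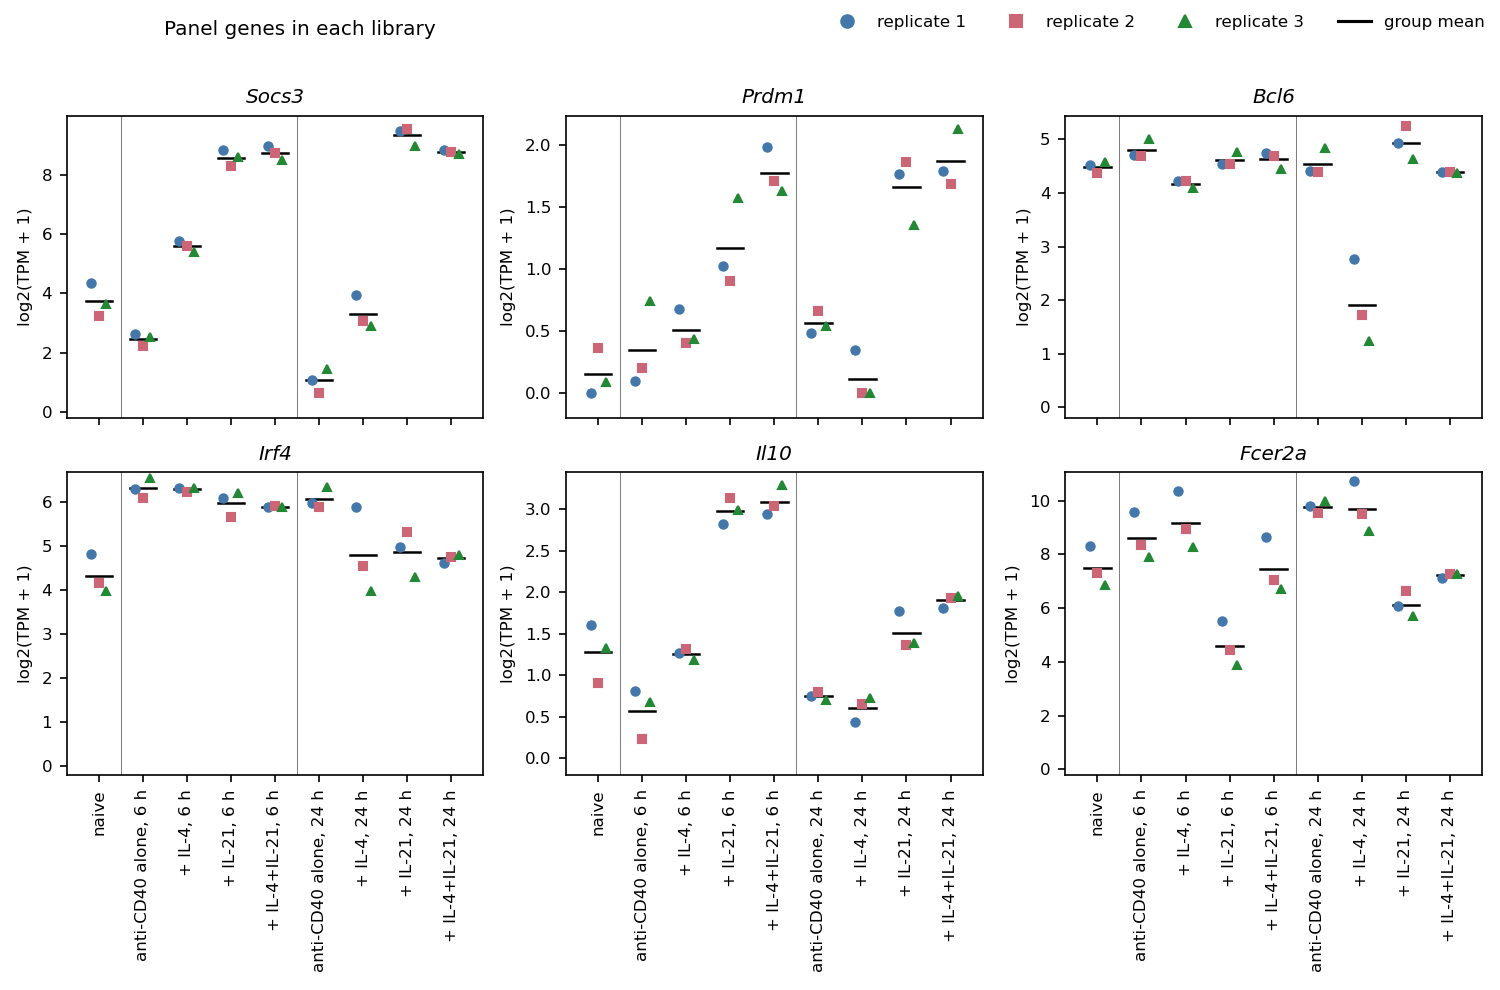
Socs3, Prdm1, Bcl6, Irf4, Il10 and Fcer2a in each library as log2(TPM + 1), with the group mean as a bar and the marker giving the replicate number. Cytokine labels name what was added to anti-CD40.

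Of 11 measured IL-21 and STAT3 response genes, 9 rose at 6 h, none fell and 2 were not called (10 called when adjusted over the list alone), with a median of 1.35 (adjusted p = 2.89e-11). With an estimated correlation that list was not called (adjusted p = 0.0835). SOCS and cytokine feedback genes moved up (6 of 13 rose, Cish and Ptpn1 among them, 1 fell and 6 were not called, 8 when adjusted over the list alone, adjusted p = 0.000358, adjusted p = 0.348 with an estimated correlation). MYC targets and ribosome biogenesis genes rose in 6 of 18 cases, for example Ncl (1.01 ± 0.17) and Gnl3 (0.86 ± 0.22), with 12 not called (9 when adjusted over the list alone). Their median was 0.70 (adjusted p = 0.000252, adjusted p = 0.305 with an estimated correlation). Among 12 p53 targets 6 rose, including Cdkn1a (1.75 ± 0.25) and Plk2 (1.52 ± 0.24), and Sesn1 fell (-2.44 ± 0.15), with 5 not called and 10 called when adjusted over the list alone (median 0.78, adjusted p = 0.00743, adjusted p = 0.285 with an estimated correlation). Anti-apoptotic genes had a median of -0.58: Bcl2a1b, Bcl2a1d and Bcl2l1 fell, Cflar rose (0.75 ± 0.14) and 6 of 10 were not called (7 called when adjusted over the list alone, adjusted p = 0.000895, adjusted p = 0.0835 with an estimated correlation). Of 9 genes for pro-apoptotic BCL2 family members and death receptors, 4 rose, including Bcl2l11 and Pmaip1 (1.36 ± 0.20), and 5 were not called (6 when adjusted over the list alone), but the list was not called (adjusted p = 0.127). Mature B cell identity genes fell in 6 of 14 cases, such as Ms4a1, Cr2 and Cd79a (-2.48 ± 0.53), and rose in 2, Bach2 (1.33 ± 0.28) and Ebf1, with 6 not called (8 when adjusted over the list alone). The median was -0.60 (adjusted p = 0.000895, adjusted p = 0.374 with an estimated correlation). Immunoglobulin constant genes had 3 of 11 lower, Iglc1 (-1.58 ± 0.26), Iglc2 and Igkc, and 8 not called (4 when adjusted over the list alone). Their median was -0.61 (adjusted p = 0.000386, adjusted p = 0.117 with an estimated correlation). Cholesterol synthesis genes had 3 of 16 lower, Dhcr7, Mvd and Cyp51, and 13 not called (8 when adjusted over the list alone). The median lay at -0.64 (adjusted p = 3.51e-05, adjusted p = 0.285 with an estimated correlation).

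After 24 h with anti-CD40 and IL-21, Socs3 was at 653 ± 131 TPM against 1.15 ± 0.608 with anti-CD40 alone, a rise of 8.27 ± 0.27 (adjusted p = 1.95e-15). Ffar2, for a receptor of short-chain fatty acids, rose to 69.1 from 1.08 TPM (5.09 ± 0.22), and Tbx21 (ENSMUSG00000001444, chr11:97098071-97115331) to 40.3 ± 5.89 from 0.409 ± 0.196 TPM (4.87 ± 0.21). Ier5l (4.81 ± 0.24), Rflnb (4.35 ± 0.28), Jun (4.29 ± 0.29), the cell cycle inhibitor gene Cdkn2d (3.26 ± 0.23) and the costimulatory gene Cd86 (3.11 ± 0.21) followed. Cd36 fell most, to 1.52 from 163 ± 2.86 TPM (-6.23 ± 0.40). Fam129c (-4.73 ± 0.28), Marcks (-4.42 ± 0.22), the IL-9 receptor gene Il9r (-4.14 ± 0.33), the chemokine gene Ccl22 (-3.29 ± 0.36), Slamf7 (-3.26 ± 0.17) and Cd80 (-2.66 ± 0.21) also fell. Fcer2a was at 71.6 ± 23.7 against 882 ± 137 TPM (-3.64 ± 0.58, adjusted p = 6.85e-05). Prdm1 rose to 2.19 ± 0.566 from 0.478 ± 0.095 TPM (1.10 ± 0.21, adjusted p = 0.000583), Il21r to 462 from 127 TPM (1.84 ± 0.36, adjusted p = 0.000576) and Il10 by 0.76 ± 0.20 (adjusted p = 0.00667). Irf4 fell (-1.21 ± 0.33, adjusted p = 0.00967), a call that ended without replicate 3 with IL-21. Bcl6 was at 30.1 against 22.7 TPM (0.38 ± 0.25, adjusted p = 0.287), and Myc (-0.14 ± 0.34), Xbp1 (-0.12 ± 0.37), Pax5 (-0.32 ± 0.38) and Il4ra (0.15 ± 0.45) were not called. Of 2936 called genes, 2167 were higher and 769 lower, and 1424 changed at least 2-fold. The higher share of 73.8% became 57.5% after median-of-ratios rescaling, which moved the median of all genes from 0.23 to 0.022, and 58.3% after mitochondrial, ribosomal protein and pseudogene transcripts were left out. Ribosomal protein transcripts made up 17.04% to 22.31% of the libraries with IL-21 and 23.14% to 27.08% of those without it.

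At 24 h the median of all genes with IL-21 and anti-CD40 was 0.23, and list medians in this paragraph are given relative to it. All 18 measured G2 and mitosis genes rose, among them Plk1 (3.07 ± 0.41), Ccnb1 (2.83 ± 0.46) and Ccnb2 (2.80 ± 0.30), with 18 called when adjusted over the list alone (median 1.99, adjusted p = 6.98e-15, adjusted p = 0.0267 with an estimated correlation). S phase and DNA replication genes rose in 18 of 20 cases, including Ccne1 (2.97 ± 0.32), Mcm3 (2.74 ± 0.60) and Rrm2 (2.35 ± 0.46), with 2 not called (18 when adjusted over the list alone). Together they had a median of 1.40 (adjusted p = 2.29e-10, adjusted p = 0.0208 with an estimated correlation). T-bet and atypical B cell genes rose in 6 of 9 cases, with Tbx21, Zeb2 (2.74 ± 0.33) and Zbtb32 (2.69 ± 0.23) in front and 3 not called (7 when adjusted over the list alone). As a list they had a median of 1.51 (adjusted p = 0.000109, adjusted p = 0.0208 with an estimated correlation). Endoplasmic reticulum stress and chaperone genes rose in 10 of 15 cases, for example Sdf2l1 (1.88 ± 0.26) and Creld2 (1.32 ± 0.28), with 5 not called (10 when adjusted over the list alone). The median over the list was 0.59 (adjusted p = 0.00217, adjusted p = 0.628 with an estimated correlation). Glycolysis genes rose in 6 of 15, with Ldha at 1.96 ± 0.27 and Pgam1 at 1.39 ± 0.30, and 9 were not called (8 when adjusted over the list alone). All measured members had a median of 0.59 (adjusted p = 0.0323, adjusted p = 0.642 with an estimated correlation). The IL-21 and STAT3 response genes rose in 10 of 11 cases, Pim1 (2.06 ± 0.29) and Bcl3 (2.26 ± 0.35) among them, and 1 was not called (10 when adjusted over the list alone). Across the members the median was 1.38 (adjusted p = 1.56e-08, adjusted p = 0.0537 with an estimated correlation). Plasma cell program genes divided into 5 that rose, Prdm1, Sdc1 (0.93 ± 0.23) and Derl3 included, 3 that fell, Mzb1 (-1.39 ± 0.14) and Irf4 included, and 4 not called (8 when adjusted over the list alone). The median of that list was 0.27, whereas its test pointed down (adjusted p = 0.514). Anti-apoptotic genes fell in 5 of 10 cases, Bcl2a1b (-2.40 ± 0.23) and Bcl2a1d (-1.87 ± 0.24) among them, with 1 higher and 4 not called (6 when adjusted over the list alone). Members had a median of -0.997 (adjusted p = 0.0002, adjusted p = 0.0254 with an estimated correlation). CD40 and NF-kB response genes fell in 5 of 16 and rose in 1, with 10 not called, Tnfaip3 (-1.93 ± 0.41) and Cd80 among those that fell (6 when adjusted over the list alone). The whole list had a median of -0.42 (adjusted p = 0.0002, adjusted p = 0.287 with an estimated correlation). Cyclin-dependent kinase inhibitor genes had 3 of 6 higher, Cdkn2d, Cdkn2c (1.02 ± 0.23) and Cdkn1a, and Cdkn1b (-0.74 ± 0.20) and Cdkn2b lower, with 1 not called (5 when adjusted over the list alone, adjusted p = 0.816). Germinal centre genes had 3 of 10 higher, 3 lower and 4 not called, Mef2b (1.88 ± 0.38) above and Rgs13 below (7 when adjusted over the list alone, adjusted p = 0.81). Mitochondrially encoded genes had mt-Co1 lower and 12 of 13 not called (0 when adjusted over the list alone). For the list the median was -0.75 (adjusted p = 0.00217, adjusted p = 0.628 with an estimated correlation).

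**Figure D3:**
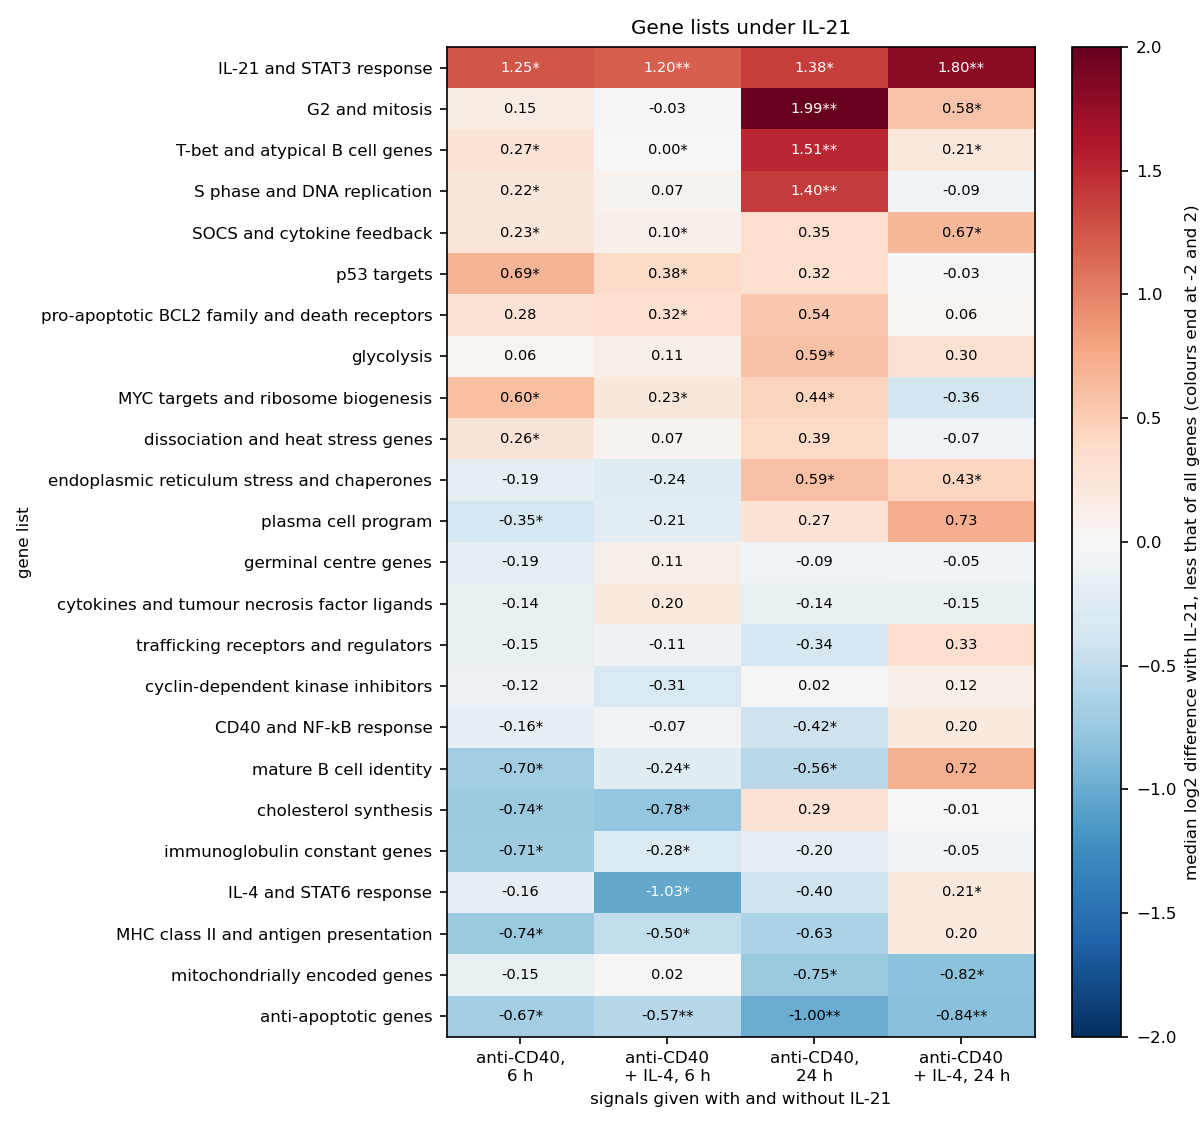
Median log2 difference of gene lists minus the median of all genes in the 4 IL-21 comparisons, markers of other cells not shown. One asterisk marks a call of the list test with the preset correlation and a double asterisk a call that also held with an estimated correlation. Among the results shown, median-of-ratios rescaling changed the direction of the test, with no call before or after, for germinal centre genes and p53 targets with anti-CD40 at 24 h, mitochondrially encoded genes with IL-4 at 6 h and MHC class II genes with IL-4 at 24 h.

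With IL-4 in the culture, 6 h of IL-21 raised Slpi (ENSMUSG00000017002, chr2:164354070-164389095), which encodes a secreted protease inhibitor, to 35.7 ± 12.7 from 1.00 ± 0.713 TPM (4.20 ± 0.32). Epb41l4b (4.02 ± 0.24), Satb1 (3.21 ± 0.30), Gem (2.99 ± 0.15), Muc1 (2.70 ± 0.30), Batf (2.59 ± 0.12) and Bcl2l11 (2.53 ± 0.23) rose next. Socs3 reached 432 ± 69.8 TPM, against 47.3 ± 6.27 TPM with anti-CD40 and IL-4 (3.16 ± 0.27, adjusted p = 9.83e-08). Il10 rose to 7.59 from 1.39 TPM (1.84 ± 0.20, adjusted p = 1.7e-06), Tbx21 by 2.04 ± 0.21 and Prdm1 to 2.44 from 0.425 TPM (1.27 ± 0.21, adjusted p = 0.000629). Falls were led by Id1, for an inhibitor of DNA-binding factors, at 1.48 against 13.9 TPM (-2.63 ± 0.27), Lad1 (-2.48 ± 0.31), Nebl (-2.39 ± 0.31), Ms4a4c (-2.36 ± 0.26), Bcl2a1b (-2.33 ± 0.23) and Cr2 (-2.26 ± 0.31). Ms4a1 was at 95.4 against 376 TPM (-1.97 ± 0.19). Fcer2a was at 401.1, 131.7 and 102.4 TPM with both cytokines against 1300, 492 and 304.7 TPM in the libraries of the same replicate numbers, and was not called (-1.72 ± 0.58, adjusted p = 0.159). Il21r (1.24 ± 0.36, adjusted p = 0.071), Pax5 (-1.09 ± 0.38, adjusted p = 0.18), Bcl6 (0.46 ± 0.25, adjusted p = 0.617), Irf4 (-0.39 ± 0.33, adjusted p = 0.82), Myc, Xbp1 and Il4ra were not called. With the replicate number as a block Fcer2a (adjusted p = 0.0106) and Il21r (adjusted p = 0.00401) were called. This comparison called 308 genes, 152 higher and 156 lower, with 206 changed at least 2-fold. The count was 550 after median-of-ratios rescaling and 561 without the 2 replicate 1 libraries.

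IL-21 and STAT3 response genes rose in 7 of 11 cases at 6 h with IL-4, Batf and Socs3 among them, with 4 not called (8 when adjusted over the list alone). Their median was 1.27 (adjusted p = 3.7e-18, adjusted p = 0.00521 with an estimated correlation). Anti-apoptotic genes fell in 3 of 10, Bcl2a1b, Bcl2l1 (-2.02 ± 0.31) and Bcl2a1d (-1.97 ± 0.24), with 7 not called (5 when adjusted over the list alone). The list median was -0.51 (adjusted p = 2.01e-07, adjusted p = 0.00477 with an estimated correlation). IL-4 and STAT6 response genes fell in 4 of 12, such as Ccl22 (-2.24 ± 0.36) and Ighe, the constant gene of IgE (-1.23 ± 0.30, adjusted p = 0.0254), with 8 not called (7 when adjusted over the list alone). Together they had a median of -0.97 (adjusted p = 1.27e-06, adjusted p = 0.171 with an estimated correlation). Cholesterol synthesis genes fell in 3 of 16, Mvd, Cyp51 and Idi1, with 13 not called (5 when adjusted over the list alone). As a list they had a median of -0.71 (adjusted p = 5.69e-08, adjusted p = 0.171 with an estimated correlation). T-bet and atypical B cell genes rose in 4 of 9, Tbx21 and Zbtb32 (1.45 ± 0.23) among them, with 5 not called (4 when adjusted over the list alone). The median over the list was 0.06 (adjusted p = 0.00216, adjusted p = 0.0543 with an estimated correlation). No gene of the S phase list (adjusted p = 0.64) or of the G2 and mitosis list (adjusted p = 0.959) was called.

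At 24 h with anti-CD40 and IL-4, IL-21 raised Slpi to 701 ± 63.2 from 6.08 ± 2.03 TPM (6.66 ± 0.32), Socs3 to 435 ± 20.9 from 9.44 ± 4.33 TPM (5.46 ± 0.27, adjusted p = 4.26e-12) and Ido1, for a tryptophan-degrading enzyme, to 46 from 0.247 TPM (5.24 ± 0.17). B3gnt7 (4.84 ± 0.45), S100a6, for a calcium-binding protein (4.69 ± 0.24), Pltp, for a phospholipid transfer protein (4.26 ± 0.31), and Cdkn2d (4.18 ± 0.23) followed. Bcl6 (ENSMUSG00000022508, chr16:23965052-23988852), for a repressor needed in germinal centre B cells, was at 20.05, 19.9 and 19.7 TPM with both cytokines and 5.84, 2.293 and 1.354 TPM with anti-CD40 and IL-4 (2.47 ± 0.25, adjusted p = 2.25e-07). Prdm1 was at 2.453, 2.207 and 3.365 TPM with both cytokines, and without IL-21 at 0.2692 TPM in 1 library and listed at 0 in the other 2 (1.75 ± 0.21, adjusted p = 3.08e-06). Il21r (2.18 ± 0.36), Bach2 (2.83 ± 0.28), Klf2 (2.67 ± 0.32), Foxo1 (1.86 ± 0.30) and Il10 (1.30 ± 0.20) rose too. Nebl (-4.11 ± 0.31), the chemokine genes Ccl22 (-3.70 ± 0.36) and Ccl17 (-3.43 ± 0.23), the IL-5 receptor gene Il5ra (-3.39 ± 0.16), Slamf7 (-3.09 ± 0.17), Bcl2a1b (-2.66 ± 0.23) and Fcer2a (-2.46 ± 0.58, adjusted p = 0.00467) fell. Ighe (ENSMUSG00000087642, chr12:113269260-113273248) fell by 2.79 ± 0.30 (adjusted p = 6.28e-07), to 1.98 TPM. Irf4 (-0.08 ± 0.33), Myc (-0.10 ± 0.34), Xbp1 (0.64 ± 0.37, adjusted p = 0.198), Pax5 (0.56 ± 0.38, adjusted p = 0.284) and Il4ra (1.09 ± 0.45, adjusted p = 0.0815) were not called, though Il4ra was with the replicate number as a block (adjusted p = 0.0126). Of 2941 called genes 2651 were higher and 290 lower, with 1619 changed at least 2-fold. The higher share of 90.1% was 50.9% after median-of-ratios rescaling, which took the median of all genes from 0.382 to 0.007 and called 1294 genes higher and 1246 lower. The control group of this comparison contained the library with 7.89% mitochondrial transcripts: the count was 5634 without that library (replicate 1), 1106 without replicate 2 and 962 without replicate 3 of anti-CD40 and IL-4, 1586 without replicate 2 and 1614 without replicate 3 of both cytokines, 5890 without the 2 replicate 1 libraries, and 342 when only the 2 compared groups were in the fit.

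Relative to the all-gene median of 0.382, IL-21 and STAT3 response genes rose in 10 of 11 cases at 24 h with IL-4, with 1 not called (11 when adjusted over the list alone). All measured members had a median of 1.80 (adjusted p = 2.02e-11, adjusted p = 0.0396 with an estimated correlation). Anti-apoptotic genes fell in 5 of 10, Bcl2a1b, Bcl2a1d (-1.97 ± 0.24) and Bcl2l1 (-1.91 ± 0.31) in front, with 1 higher and 4 not called (6 when adjusted over the list alone). Across the members the median was -0.84 (adjusted p = 4.83e-06, adjusted p = 0.0111 with an estimated correlation). SOCS and cytokine feedback genes rose in 8 of 13, Socs1 (2.24 ± 0.32) and Ptpn1 (2.60 ± 0.33) included, with 5 not called (10 when adjusted over the list alone). Members had a median of 0.67 (adjusted p = 0.000569, adjusted p = 0.664 with an estimated correlation). T-bet and atypical B cell genes rose in 5 of 9, with Zeb2 at 3.31 ± 0.33 and Tbx21 at 2.72 ± 0.21, and 4 were not called (6 when adjusted over the list alone). The whole list had a median of 0.21 (adjusted p = 0.0106, adjusted p = 0.168 with an estimated correlation). G2 and mitosis genes rose in 10 of 18, Plk1 (1.94 ± 0.41) among them, with 8 not called (12 when adjusted over the list alone). For the list the median was 0.58 (adjusted p = 0.01, adjusted p = 0.768 with an estimated correlation). That call ended when mitochondrial, ribosomal protein and pseudogene transcripts were left out (adjusted p = 0.0591). S phase genes had 2 of 20 higher, 1 lower and 17 not called (3 when adjusted over the list alone, adjusted p = 0.516). Endoplasmic reticulum stress genes rose in 8 of 15, for example Creld2 (1.21 ± 0.28) and Dnajb9 (1.07 ± 0.25), with 7 not called (11 when adjusted over the list alone). Their median was 0.43 (adjusted p = 0.0115, adjusted p = 0.768 with an estimated correlation), a call lost after median-of-ratios rescaling (adjusted p = 0.155). IL-4 and STAT6 response genes divided into 3 that rose and 5 that fell, Ccl17, Ighe and Fcer2a among the latter, with 4 not called (9 when adjusted over the list alone). Their median was 0.21 and their mean below 0, and the test pointed down (adjusted p = 0.00602, adjusted p = 0.684 with an estimated correlation, adjusted p = 0.117 after median-of-ratios rescaling). Trafficking receptor genes rose in 5 of 11, Klf2 and Ccr6 (2.47 ± 0.39) included, and 6 were not called (5 when adjusted over the list alone, adjusted p = 0.0776, adjusted p = 0.0297 with the replicate block). Mature B cell identity genes rose in 8 of 14, Bach2 and Cd22 (2.30 ± 0.48) among them, and fell in 2, Ms4a1 and Cr2, with 4 not called (10 when adjusted over the list alone, adjusted p = 0.506). The fall of this list with IL-4 at 24 h, given below, rests on the same libraries with anti-CD40 and IL-4. Cytokine and tumour necrosis factor ligand genes had 3 of 8 higher, 2 lower and 3 not called, Il10 above and Ltb (-1.88 ± 0.23) below (5 when adjusted over the list alone, adjusted p = 0.514). MHC class II and antigen presentation genes had 2 of 12 higher, Ciita (1.10 ± 0.32) among them, and 10 not called (2 when adjusted over the list alone), and a test that pointed up (adjusted p = 0.779) and pointed down after either rescaling. Mitochondrially encoded genes had none called in 13, also when adjusted over the list alone, and a median of -0.82 (adjusted p = 3.79e-05, adjusted p = 0.627 with an estimated correlation).

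Across 12147 genes the IL-21 effects with and without IL-4, which shared no libraries, had a correlation across genes of 0.566 at 6 h (rank correlation 0.533) and 0.48 at 24 h (0.401), genes not being independent replicates. At 6 h 133 genes rose in both comparisons against 11.3 expected if the calls were unrelated, 127 fell in both against 7.295, and 0 changed in opposite directions. Batf, Gem and Satb1 were among those that rose in both, and Bcl2a1b, Ms4a1 and Cr2 among those that fell. At 24 h 833 genes rose in both against 472.933 expected, 168 fell in both against 18.359 and 45 went in opposite directions. Both comparisons use the same estimate of each gene's spread. Calls can therefore overlap more than expected here even with unrelated effects. The shared spread does not favour the same direction over the opposite one. At 24 h, all-gene medians of 0.23 without IL-4 and 0.382 with it also add to the joint rises. Among genes called in either comparison the slope of the effect with IL-4 on that without it was 0.459 over 1519 genes at 6 h and 0.604 over 4831 genes at 24 h. At 6 h 1471 genes were called without IL-4 and 308 with it. Choosing genes by a call tends to overstate the effect in that comparison. The slope can therefore come out low without a true difference.

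**Figure D4:**
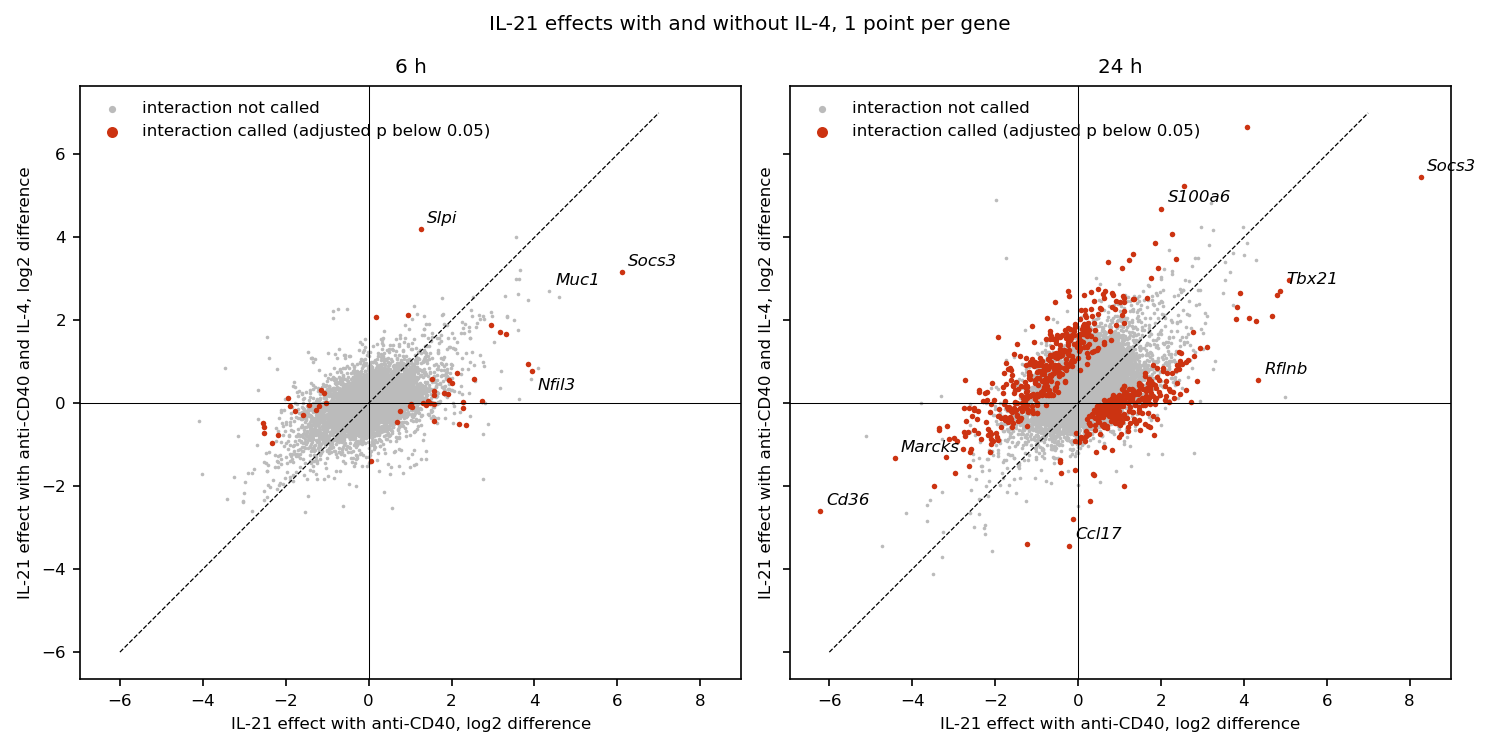
IL-21 effect with IL-4 against that without IL-4 for each gene at 6 h and 24 h, with genes called for the interaction in red and the dashed line where the effects were equal.

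The interaction of IL-21 with IL-4 at 6 h, the effect with IL-4 minus that without, was among the largest for Nfil3 (-3.16 ± 0.39, adjusted p = 0.000445), Socs3 (-2.95 ± 0.39, adjusted p = 0.000445) and Slpi (2.94 ± 0.45, adjusted p = 0.00209). With IL-21, Socs3 was at 459.9, 315.7 and 385 TPM without IL-4 and 502.9, 429.7 and 363.3 TPM with it. Without IL-21 it was at 5.208, 3.699 and 4.837 against 53.25, 47.95 and 40.76 TPM. Its interaction was thus a smaller fold change from a higher start, not a lower level with IL-21. IL-4 by itself held Nfil3 at 113 TPM and Cish, which encodes another cytokine signalling suppressor, at 93.4 TPM, and Cish was at 97.2 TPM with both cytokines (-2.68 ± 0.43, adjusted p = 0.0034). The call of Socs1 (-2.39 ± 0.45, adjusted p = 0.0165) ended without replicate 3 of both cytokines, that of Il7r (-1.54 ± 0.23) with a pseudocount of 0.1, and those of Cd86 (-1.43 ± 0.30) and Cflar (-0.93 ± 0.19) after rescaling. Of 50 called genes 18 were higher and 32 lower, 48 of them at least 2-fold, and 30 had an IL-21 effect of the same sign that was smaller with IL-4, 3 a larger one and 17 one of opposite sign, none of these called in both comparisons. IL-4 and STAT6 response genes had 3 of 12 lower, Nfil3, Cish and Socs1, and 9 not called (5 when adjusted over the list alone). The list median was -0.80 (adjusted p = 8.29e-05, adjusted p = 0.518 with an estimated correlation). The count was 96 with the replicate numbers as a block, 24 with a pseudocount of 0.1, 23 with a filter at 5 TPM, 219 with no filter, 87 after removal of a trend with GC content and length and 98 without the 2 replicate 1 libraries. It was 24, 32 and 23 without replicate 1, 2 or 3 of anti-CD40, 29 and 24 without replicate 2 or 3 with IL-4, 24 without replicate 2 with IL-21, and 21, 28 and 27 without replicate 1, 2 or 3 of both cytokines.

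At 24 h the interaction was positive for Cd36 (3.63 ± 0.57), the NF-kB inhibitor gene Tnfaip3 (3.53 ± 0.58), Marcks (3.10 ± 0.32, adjusted p = 2.77e-06), Gbp2 (2.69 ± 0.28), Bcl6 (2.09 ± 0.36, adjusted p = 0.000876) and Cd80 (1.98 ± 0.30). It was negative for Rflnb (-3.78 ± 0.40), Ccl17 (-3.21 ± 0.33), Tmem176b (-3.10 ± 0.57), Socs3 (-2.81 ± 0.39, adjusted p = 0.000102), Ighe (-2.68 ± 0.43), Tbx21 (-2.15 ± 0.30, adjusted p = 0.000104), the cyclin A2 gene Ccna2 (-1.89 ± 0.26) and Cd86 (-1.74 ± 0.30). The Tbx21 call ended with a pseudocount of 0.1. Relative to the all-gene median of 0.19, S phase genes had 6 of 20 lower, Tyms (-1.79 ± 0.31) and Gins1 (-1.87 ± 0.34) among them, and 14 not called (16 when adjusted over the list alone). The median lay at -1.53 (adjusted p = 1.58e-14, adjusted p = 0.00607 with an estimated correlation). G2 and mitosis genes had 6 of 18 lower, Ccna2, Kif11 and Bub1 included, and 12 not called (12 when adjusted over the list alone). Together they had a median of -1.34 (adjusted p = 1.1e-13, adjusted p = 0.0782 with an estimated correlation). Mature B cell identity genes had 2 of 14 higher, 0 lower and 12 not called (9 when adjusted over the list alone). As a list they had a median of 0.97 (adjusted p = 6.44e-05, adjusted p = 0.32 with an estimated correlation). CD40 and NF-kB response genes had 4 of 16 higher and 12 not called, Tnfaip3 and Cd80 among the former (5 when adjusted over the list alone). The median over the list was 0.65 (adjusted p = 0.000649, adjusted p = 0.32 with an estimated correlation). Of 705 called genes 404 were higher and 301 lower, 562 of them at least 2-fold; 228 had a smaller and 97 a larger IL-21 effect of the same sign with IL-4, 378 one of opposite sign, of which 45 were called in both comparisons, and 2 an effect of 0 with IL-4. The higher share of 57.3% was 44.7% after median-of-ratios rescaling (605 of 1353 genes). The count was 2460 without replicate 1 of anti-CD40 and IL-4, which had 7.89% mitochondrial transcripts, 3015 without the 2 replicate 1 libraries and 289 with only the compared groups in the fit.

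Between 6 h and 24 h the IL-21 effect with anti-CD40 grew for Pltp (3.89 ± 0.43), Rflnb (3.67 ± 0.40), Serpinb7 (3.47 ± 0.26) and Socs3 (2.15 ± 0.39), and moved down for Epb41l4b (-3.88 ± 0.34), Marcks (-3.65 ± 0.32), Cd36 (-2.99 ± 0.57) and Il10 (-1.66 ± 0.28). With anti-CD40 and IL-4 it grew for S100a6 (6.02 ± 0.34), Pltp (4.15 ± 0.43), Vim (4.12 ± 0.40), Socs3 (2.30 ± 0.39) and Bcl6 (2.02 ± 0.36), and moved down for Epb41l4b (-4.12 ± 0.34) and Slamf7 (-2.97 ± 0.24). For Socs3 and Bcl6 this came with a fall of the level without IL-21. Socs3 fell there from 53.25, 47.95 and 40.76 to 14.42, 7.446 and 6.47 TPM. Bcl6 fell from 17.58, 17.58 and 16.08 to 5.84, 2.293 and 1.354 TPM. With both cytokines Socs3 was at 502.9, 429.7 and 363.3, then at 455.7, 434.4 and 413.9 TPM. Bcl6 was at 25.88, 24.99 and 20.82, then at 20.05, 19.9 and 19.7 TPM. Without IL-4 539 genes differed between the times, 376 higher at 24 h, around a median of 0.124 for all genes. With IL-4 515 differed, 445 of them higher, around a median of 0.331. The share of 86.4% higher with IL-4 was 62.8% after median-of-ratios rescaling (489 of 779 genes). The count with IL-4 was 3408, 262 and 282 without replicate 1, 2 or 3 of the 24 h group with IL-4, of which replicate 1 had 7.89% mitochondrial transcripts, 309 without replicate 1 of the 6 h group with IL-4, 311 without replicate 3 of both cytokines at 6 h and 314 and 330 without replicate 2 or 3 of both at 24 h. It was 3909 without the 2 replicate 1 libraries and 206 with only the compared groups in the fit. Without IL-4 the count was 1040 with those 2 libraries left out and 838 with the whole 24 h group of anti-CD40 and IL-4 left out of the fit.

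IL-4 added to anti-CD40 for 6 h raised Cish (ENSMUSG00000032578, chr9:107296026-107302784) to 93.4 from 0.809 TPM (5.71 ± 0.31, adjusted p = 2.61e-11), Nfil3 to 113 from 1.41 TPM (5.57 ± 0.28), Pkib (5.03 ± 0.21), Socs1 (3.99 ± 0.32), the IgG1 constant gene Ighg1 to 27.1 from 1.45 TPM (3.56 ± 0.42) and Socs3 (3.12 ± 0.27). Fcrl1 fell to 16.8 from 113 TPM (-2.71 ± 0.23), with Ccr6 (-2.62 ± 0.39), Fcrla (-2.59 ± 0.43) and the IL-12 subunit gene Il12a (-2.05 ± 0.24). IL-4 and STAT6 response genes rose in 7 of 12 cases, Cish, Nfil3 and Ighg1 among them, with 5 not called (9 when adjusted over the list alone). All measured members had a median of 1.99 (adjusted p = 2.17e-21, adjusted p = 0.0112 with an estimated correlation). Endoplasmic reticulum stress genes rose in 2 of 15, Manf (1.33 ± 0.19) and Sdf2l1 (1.31 ± 0.26), with 13 not called (8 when adjusted over the list alone). Across the members the median was 0.68 (adjusted p = 4.77e-08, adjusted p = 0.269 with an estimated correlation). MHC class II genes rose in 4 of 12, H2-DMb1 included, and fell in 1, with 7 not called (7 when adjusted over the list alone). Members had a median of 0.81 (adjusted p = 0.000988, adjusted p = 0.387 with an estimated correlation). In all 491 genes were called, 200 higher and 291 lower, 329 of them at least 2-fold. The count was 761 after median-of-ratios rescaling and 768 without the 2 replicate 1 libraries.

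At 24 h IL-4 raised Nfil3 (5.81 ± 0.28), Cish (5.28 ± 0.31), Ighg1 (5.28 ± 0.42), Ighe (4.15 ± 0.30), Socs2 (3.76 ± 0.46) and the sterol synthesis gene Idi1, at 360 against 63.4 TPM (2.46 ± 0.16). Cr2 fell to 7.21 from 140 TPM (-4.25 ± 0.31), and Fcrla (-4.15 ± 0.43), Il12a (-4.11 ± 0.24), Trim7 (-3.95 ± 0.35), Ccr6 (-3.75 ± 0.39), the lymphotoxin beta gene Ltb (-2.96 ± 0.23) and Bcl6 (-2.64 ± 0.25, adjusted p = 8.15e-08) fell with it. Relative to the all-gene median of -0.308, IL-4 and STAT6 response genes rose in 8 of 12, fell in 1 and were not called in 3 (9 when adjusted over the list alone). The whole list had a median of 2.43 (adjusted p = 4.02e-12, adjusted p = 0.0621 with an estimated correlation). S phase genes rose in 10 of 20, Tyms (1.97 ± 0.22) and Gins1 (1.83 ± 0.24) included, with 10 not called (12 when adjusted over the list alone). For the list the median was 1.25 (adjusted p = 2.08e-10, adjusted p = 0.0335 with an estimated correlation). Mature B cell identity genes fell in 12 of 14, Cr2 and Spib (-2.10 ± 0.34) among them, with 2 not called (12 when adjusted over the list alone). Their median was -1.10 (adjusted p = 6.26e-05, adjusted p = 0.341 with an estimated correlation). CD40 and NF-kB response genes fell in 10 of 16, Cd80 (-2.10 ± 0.21) and Nfkbie (-1.89 ± 0.30) included, Cd83 rose (0.93 ± 0.14) and 5 were not called (12 when adjusted over the list alone). The list median was -0.89 (adjusted p = 0.0138, adjusted p = 0.536 with an estimated correlation). Of 3816 called genes 1006 were higher and 2810 lower, 2068 of them at least 2-fold. The higher share of 26.4% was 51% after median-of-ratios rescaling, which moved the all-gene median to -0.027 (2171 higher and 2087 lower). The count was 2514 and 2452 without replicate 2 or 3 of anti-CD40 and IL-4, whose replicate 1 had 7.89% mitochondrial transcripts, 2409 without replicate 3 of anti-CD40, 5979 without the 2 replicate 1 libraries and 913 with only the compared groups in the fit.

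Genes that IL-4 changed at least 2-fold at 6 h were then followed at 24 h, in libraries not used to choose them. Of 146 genes raised by IL-4, 63 rose and 17 fell with IL-21 and IL-4, with a median of 0.617 against 0.384 for the other genes (adjusted p = 0.0962), and as a list they were called with no filter (adjusted p = 5.11e-05). Of 183 genes lowered by IL-4, Ltb and Ccr6 among them, 41 rose and 22 fell. Their median of 0.122 lay below the 0.384 of the other genes, and the test pointed down (adjusted p = 0.0191, adjusted p = 0.857 with an estimated correlation). That call ended with genes chosen at adjusted p alone (0.141, adjusted p = 0.0543), with the replicate block (0.158, adjusted p = 0.0561), with a pseudocount of 0.1 (0.289, adjusted p = 0.133) and with no filter (0.097, adjusted p = 0.458). It also ended after median-of-ratios rescaling (-0.202, adjusted p = 0.0705), which moved the median of all genes from 0.382 to 0.007. In the reverse choice, the 339 genes raised at 24 h had a median of 0.034 at 6 h (11 rose, 14 fell, adjusted p = 0.748) and the 1729 lowered genes one of -0.018 against 0.077 for the other genes (33 rose, 58 fell, adjusted p = 0.00721, adjusted p = 0.857 with an estimated correlation). The last call ended with a pseudocount of 0.1 (0.018, adjusted p = 0.0745) and with genes chosen at adjusted p alone (0.016, adjusted p = 0.0543).

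Anti-CD40 alone for 6 h, against naive cells, raised the p53 target gene Phlda3 to 55.2 from 0.214 TPM (5.53 ± 0.23), the IL-2 receptor gene Il2ra (4.77 ± 0.22), Cdkn1a (4.54 ± 0.25), Bcl2l1 to 28 from 0.639 TPM (4.14 ± 0.31), Bcl2a1b (3.30 ± 0.23), Cd83 to 847 from 162 TPM (2.38 ± 0.14) and Irf4 to 79.3 from 19.7 TPM (1.99 ± 0.33). Hspa1b fell to 2.71 from 674 TPM (-7.50 ± 0.28), with Fos (-7.28 ± 0.27), the egress receptor gene S1pr1, at 3.65 against 106 TPM (-4.54 ± 0.27), Klf2 (-3.98 ± 0.32), Cd22 (-3.89 ± 0.48) and Cr2 (-3.55 ± 0.31). The integrin gene Itgb7 was listed at 0 in all 3 libraries. CD40 and NF-kB response genes rose in 13 of 16 with 3 not called (15 when adjusted over the list alone). Relative to the all-gene median of 0.057 theirs lay at 1.25 (adjusted p = 1.3e-06, adjusted p = 0.106 with an estimated correlation). MYC targets rose in 13 of 18, Nop16 (2.59 ± 0.21) included, with 5 not called (14 when adjusted over the list alone). Together they had a median of 1.60 (adjusted p = 4.77e-09, adjusted p = 0.0892 with an estimated correlation). MHC class II genes fell in 10 of 12, H2-Aa (-2.60 ± 0.35) and H2-DMb1 (-2.77 ± 0.37) among them, with 2 not called (10 when adjusted over the list alone). As a list they had a median of -2.23 (adjusted p = 1.18e-06, adjusted p = 0.119 with an estimated correlation). The 3626 called genes held 2012 higher and 1614 lower, and the higher share of 55.5% was 44% after median-of-ratios rescaling (1901 higher and 2417 lower).

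Markers of other cells moved with the culture. Summed macrophage and monocyte marker TPM was 115.3 ± 22.3 in naive cells and 2.05 to 12.37 in the stimulated groups, and that of erythroid and platelet markers 1418 ± 393 in naive cells, 136.4 to 217.3 at 6 h and 18.27 to 36.7 at 24 h. Dissociation and heat stress genes summed to 1846 ± 461 TPM in naive cells. With IL-21 they were at 359.3 ± 24.8 against 179.9 ± 10.1 TPM at 6 h (adjusted p = 0.0437, adjusted p = 0.468 with an estimated correlation) and at 377.9 ± 73.8 against 126.9 ± 21.7 TPM at 24 h (4 of 10 rose, adjusted p = 0.064). In cultures with IL-4, IL-21 had them at 349.5 ± 32 against 218.8 ± 17.1 TPM at 6 h (1 of 10 rose, adjusted p = 0.119) and at 239 ± 13.5 against 114.3 ± 62.7 TPM at 24 h (2 of 10 rose, adjusted p = 0.514). At 6 h with anti-CD40, macrophage markers fell in 5 of 6 with 1 not called (median -2.83 relative to all genes, adjusted p = 6.98e-08, adjusted p = 0.00182 with an estimated correlation), C1qa (-4.28 ± 0.23) among them. Erythroid markers fell in 8 of 8, Hbb-bs to 70.8 from 755 TPM (-3.31 ± 0.39) among them (median -2.71, adjusted p = 3.82e-08, adjusted p = 0.00027 with an estimated correlation). Dissociation and heat stress genes fell in 8 of 10 and rose in 1, with 1 not called (9 when adjusted over the list alone). All measured members had a median of -3.48 (adjusted p = 5.92e-10, adjusted p = 0.0271 with an estimated correlation). T cell markers had 2 of 4 higher with IL-21 at 6 h without IL-4, Trac (1.11 ± 0.28) among them, with 2 not called (median 0.60, adjusted p = 0.0231, adjusted p = 0.271 with an estimated correlation). With IL-21 and IL-4 at 6 h none of the 4 was called (3 when adjusted over the list alone, adjusted p = 0.0185, adjusted p = 0.188 with an estimated correlation), and with IL-4 alone at 6 h 2 of 4 rose (adjusted p = 0.011, adjusted p = 0.269 with an estimated correlation). Their summed TPM was 17.71 ± 6.83 in naive cells, 44.32 ± 29.6 with IL-4 at 24 h and 85.57 ± 10.4 with both cytokines at 24 h, where 2 of 4 rose with IL-21 (adjusted p = 0.514). Of the 11 T cell markers listed, only these 4 passed the filter. Cd3d, Cd3e, Cd3g, Trbc2, Cd4, Cd8a and Cd8b1 did not, so the sum does not show a larger share of T cells. Thy1 was at 46, 13 and 15 TPM in the 24 h libraries with anti-CD40 and IL-4. The 2 measured dendritic cell markers were not called at 24 h with IL-21 (adjusted p = 0.183). NK cell and neutrophil lists had too few measured genes to test and had group means of at most 2.73 and 0.52 TPM.

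After 24 h with anti-CD40, Rp2 (4.92 ± 0.44), Ccl22, at 55.9 against 1.42 TPM (4.52 ± 0.36), Ms4a6c (4.35 ± 0.20), Bcl2a1b (2.77 ± 0.23) and Irf4 (1.75 ± 0.33) were higher than in naive cells. Hspa1b, at 0.608 against 674 TPM (-8.69 ± 0.28), Fos (-8.12 ± 0.27), Klf2 (-4.31 ± 0.32), Jchain (-3.69 ± 0.42), S1pr1 (-3.58 ± 0.27) and Socs3 (-2.68 ± 0.27) were lower. Relative to the all-gene median of 0.249, cholesterol synthesis genes rose in 14 of 16, Fdps (2.11 ± 0.39) included, with 2 not called (15 when adjusted over the list alone). Across the members the median was 1.17 (adjusted p = 1.22e-06, adjusted p = 0.228 with an estimated correlation). S phase genes rose in 12 of 20 and Mcm3 fell (-3.66 ± 0.60), with 7 not called (14 when adjusted over the list alone). Members had a median of 0.79 (adjusted p = 0.000528, adjusted p = 0.212 with an estimated correlation). Trafficking receptor genes fell in 7 of 11, S1pr1 and Klf2 among them, and rose in 2, with 2 not called (9 when adjusted over the list alone). The whole list had a median of -1.88 (adjusted p = 2.74e-05, adjusted p = 0.244 with an estimated correlation). Of 3252 called genes 2299 were higher and 953 lower, and the higher share of 70.7% was 44.7% after median-of-ratios rescaling (1608 higher and 1989 lower).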

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

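The differences between IL-21 effects below were planned tests, flagged because the effect of IL-21 differed with IL-4 or with time; of the tests of explanations, those called added were chosen after the results were seen.

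At 24 h, 90.1% of the genes called for IL-21 with IL-4 were higher. A bias from GC content and transcript length predicted that the share would drop once that trend was removed. It was 91.4%, but the removal kept each library's mean over the genes. The median of all genes was 0.389 after it against 0.382 before. The share could therefore hardly drop, and the test cannot tell. An added test left out mitochondrial, ribosomal protein and pseudogene transcripts and gave 80.5%, which argues against a larger share of those transcripts as the main cause. A second added test asked whether replicate 1 with anti-CD40 and IL-4 was a library with IL-21, and its slope on the 6 h IL-21 effect was 0.062 of that of the libraries with IL-21 (0.052 against 0.844 over 206 genes), which argues against it. Scaling stays open: median-of-ratios rescaling gave 50.9%, but it brings the median of all genes close to 0 by construction, so that value speaks neither for nor against it.

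The IL-21 effect on the S phase genes at 24 h was lower with IL-4, where the list was not called (2 of 20 rose, 1 fell, adjusted p = 0.516). A scaling cause predicted that the difference would vanish after median-of-ratios rescaling. It was -1.591 relative to all genes, against -1.527 before. Rescaling moves all genes of a library nearly alike, so this value was almost fixed beforehand and the test cannot tell. The list median was -1.61 after rescaling and -1.34 before, where that of all genes was -0.019 and 0.19. The list thus lay below all genes on either scale, by more than a shift common to all genes. An added test of the hypothesis that IL-4 alone had already raised these genes gave 1.252 relative to all genes, in line with it, but the IL-4 effect shares libraries with the interaction. The list mean was 3.74 ± 0.20 with anti-CD40, 4.66 ± 0.46 with IL-4 (5.18, 4.46 and 4.33 in replicates 1, 2 and 3, the tests not being repeated without replicate 1), 5.39 ± 0.21 with IL-21 and 5.03 ± 0.09 with both at 24 h (n = 3), and at 6 h it was 3.03 ± 0.15 with anti-CD40 and 3.40 ± 0.06 with IL-4.

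Of the 50 genes called for the interaction at 6 h, 30 had a smaller IL-21 effect of the same sign with IL-4, and the hypothesis was that IL-4 itself moves them in the direction of IL-21. An added test compared signs with the IL-4 effect at 24 h, in other libraries: 66.7% (20 of 30) had the same sign, against 61.3% (872 of 1423) of the other genes called for IL-21 at 6 h. The test cannot tell. Relative to the median of all genes the share was 80% (24 of 30). Of these genes 14 were called for IL-4 at 24 h with the same sign and 2 with the opposite one. Neither of these measures was computed for the other genes called for IL-21 at 6 h, so they do not decide the question.

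Flagged by a difference of the IL-21 effect with and without IL-4 at 6 h were 50 genes, among them Slpi (2.94), Pglyrp1 (2.09), Crisp3 (2.07), Nid1 (1.97), Cflar (-0.93), Cd86 (-1.43), Il7r (-1.54), Socs1 (-2.39), Cish (-2.68), Olfr805 (-2.87), Socs3 (-2.95) and Nfil3 (-3.16). Lists flagged by the same test, none of them with an estimated correlation, had medians of -0.32 (IL-21 and STAT3 response), -0.80 (IL-4 and STAT6 response), 0.37 (plasma cell program), 0.26 (mature B cell identity), 0.40 (immunoglobulin constant genes), -0.29 (S phase), -0.37 (MYC targets), -0.11 (SOCS and cytokine feedback) and -0.41 (macrophage markers).

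Flagged by the same difference at 24 h were 705 genes. Above 0 were Cd36 (3.63), Tnfaip3 (3.53), Plxnd1 (3.29), Marcks (3.10), Gbp2 (2.69), Dusp5 (2.24), Bcl6 (2.09), Cd80 (1.98), Gbp3 (1.87), S1pr1 (1.87), Klf2 (1.85), Spib (1.83), Stat2 (1.75), Ighd (1.65), Creb3l2 (1.37), Socs5 (1.33), Cd79b (1.29), Il12a (1.27), Cdkn1b (1.16), Bcl2 (1.16), Sesn1 (1.13), Rel (1.12), Birc3 (1.07), Trp53inp1 (1.02), Mzb1 (0.98) and Ctss (0.91). Below 0 were Cflar (-0.68), Batf (-0.88), Ncl (-0.89), Tpi1 (-1.01), Itgax (-1.11), Nop58 (-1.29), Itgam (-1.60), Ldha (-1.69), Idi1 (-1.69), Gins2 (-1.72), Cd86 (-1.74), Bub1 (-1.78), Tyms (-1.79), Kif11 (-1.84), Gins1 (-1.87), Ccna2 (-1.89), Tbx21 (-2.15), Ighe (-2.68), Socs3 (-2.81), Tmem176b (-3.10), Ccl17 (-3.21) and Rflnb (-3.78). Flagged lists had medians of 1.16 (mature B cell identity), -1.34 (S phase), -1.15 (G2 and mitosis), -0.52 (MYC targets), 0.84 (CD40 and NF-kB response), -0.32 (T-bet and atypical B cell genes), 1.44 (trafficking receptors) and -0.22 (cholesterol synthesis), around a median of 0.19 for all genes. With an estimated correlation only the S phase list kept its call (adjusted p = 0.00607).

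Flagged by a difference of the IL-21 effect between the times were 539 genes with anti-CD40, among them Pltp (3.89), Rflnb (3.67), Serpinb7 (3.47), Socs3 (2.15), Il10 (-1.66), Cd36 (-2.99), Marcks (-3.65) and Epb41l4b (-3.88). With anti-CD40 and IL-4 they were 515, among them S100a6 (6.02), Pltp (4.15), Vim (4.12), Socs3 (2.30), Bcl6 (2.02), Socs2 (-2.72), Slamf7 (-2.97) and Epb41l4b (-4.12).

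Regroupings of the libraries were counted for each comparison. With 3 libraries against 3 there are only 10 splits, too few for a share under 0.05. The real count and the highest of the other splits were 1471 and 4 for IL-21 with anti-CD40 at 6 h, 2936 and 1 at 24 h, 308 and 2 for IL-21 with IL-4 at 6 h, 2941 and 2266 at 24 h, 491 and 1 for IL-4 at 6 h, 3816 and 4285 at 24 h, and 3626 and 1 and 3252 and 1 for anti-CD40 at 6 h and 24 h. The real grouping was first of 10 in each but IL-4 at 24 h, where 2 of 10 reached it. A split that mixes the groups puts their difference into the residual spread, which lowers its count. The counts of the other splits therefore do not show what groups without a difference would give. The split with 2266 put replicate 1 of anti-CD40 and IL-4 with replicates 2 and 3 of both cytokines, and the one with 4285 put replicate 1 of anti-CD40 and IL-4 with replicates 1 and 3 of anti-CD40. For the interactions and changes with time 100 permutations of residuals were drawn, the real one among them. As many genes as in the real data were called in 1 of 100 for the interaction at 6 h (50, highest other 11), in 4 of 100 at 24 h (705, highest other 2232), in 1 of 100 for the change with time without IL-4 (539, highest other 6) and in 4 of 100 with IL-4 (515, highest other 1691). Permutations with 2232 and 1691 genes called several times the real count, which points to a structure of the samples. Both comparisons hold the 24 h group with anti-CD40 and IL-4, while those with 11 and 6 do not. Without replicate 1 of that group, the real counts were 2460 for the interaction at 24 h and 3408 for the change with time with IL-4. What sets that group apart was not tested.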

How the results depend on the processing

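Calls of named genes were mostly the same under the alternatives, and no named gene reversed: of calls in single left-out libraries 4138 were the same, 556 weaker and 4 stronger, and after median-of-ratios rescaling 652, 52 and 5. More were lost with only the compared groups in the fit, where 548 were the same, 160 weaker and 1 stronger. Outside the fixed panel, named genes were chosen as called in the main fit, many for the largest changes. The lack of reversals was therefore largely set by that choice. Results counted as the same include panel genes called in neither fit. With an estimated correlation 17 of 108 called results of the lists used here, 1 list being left out, kept their call and 91 lost it. The list results that reversed were dendritic cell markers with anti-CD40 at 6 h (-0.804) and T cell markers with anti-CD40 at 24 h (0.027), both with no filter, where more genes enter the lists. A count-based alternative was not run, because the table holds TPM. Depth is unknown, so its limit on genes with low values could not be measured. Where no cause is given, the cause was not tested.

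Fewer libraries or residual degrees of freedom come with leaving libraries out and with fitting only the compared groups. Single libraries were left out only for the comparisons that hold them, though all libraries share an estimate of the spread. Libraries outside a comparison also move its count. Without the 24 h group of anti-CD40 and IL-4 in the fit, IL-21 with anti-CD40 at 6 h had 1928 genes. With single libraries left out the counts ran from 939 to 1262 for IL-21 with anti-CD40 at 6 h and 2057 to 2827 at 24 h, from 225 to 250 and 962 to 5634 for IL-21 with IL-4, from 21 to 43 and 501 to 2460 for the interactions, from 377 to 537 and 262 to 3408 for the changes with time without and with IL-4, from 365 to 408 and 2409 to 5697 for IL-4, and from 2999 to 3623 and 2196 to 3774 for anti-CD40. With only the compared groups in the fit the 24 h counts were 342 for IL-21 with IL-4, 289 for the interaction, 913 for IL-4 and 2167 for anti-CD40, and the change with time with IL-4 had 206.

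Median-of-ratios rescaling gave 550 genes for IL-21 with IL-4 at 6 h, 1353 for the interaction at 24 h, 779 for the change with time with IL-4 and 761 for IL-4 at 6 h, and the IL-4-lowered genes of 6 h a median of -0.202 (adjusted p = 0.0705). A pseudocount of 0.1 gave 24 for the interaction at 6 h, a correlation across genes of 0.436 at 6 h, and medians of 0.289 (adjusted p = 0.133) and 0.018 (adjusted p = 0.0745) for the genes lowered by IL-4 at 6 h and at 24 h. With no filter the counts were 3212 for IL-21 with anti-CD40 at 6 h and 219 for the interaction at 6 h, the genes raised by IL-4 at 6 h had a median of 0.617 with a call (adjusted p = 5.11e-05) and those lowered 0.097 without one (adjusted p = 0.458). A filter at 5 TPM, with fewer genes tested, gave 23 for the interaction at 6 h. Choosing IL-4-responsive genes at adjusted p alone gave 0.141 (adjusted p = 0.0543) and 0.016 (adjusted p = 0.0543) for those lowered at 6 h and 24 h. Leaving out the variance trend moved none of the counts by over 1.5 times.

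Using the replicate block changed the interaction at 6 h from 50 to 96 genes, from 48 to 84 of them at least 2-fold, and the genes lowered by IL-4 at 6 h to 0.158 (adjusted p = 0.0561). The replicate block moved no other count by over 1.5 times, though 7 results of 6 named genes and 7 results of 5 lists changed their call. Il10 for IL-4 at 6 h and anti-CD40 at 24 h, Iglc2 and Ighg2c for IL-21 with IL-4 at 6 h and 24 h and the T-bet list for anti-CD40 at 24 h lost theirs.

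Added after seeing the data, leaving out replicate 1 of the naive group and of the 24 h group with anti-CD40 and IL-4 gave 2256, 4139, 561 and 5890 genes for IL-21 with anti-CD40 at 6 h and 24 h and with IL-4 at 6 h and 24 h, 98 and 3015 for the interactions, 1040 and 3909 for the changes with time, 768 and 5979 for IL-4 and 4433 and 4716 for anti-CD40. Leaving the 24 h group with anti-CD40 and IL-4 out of the fit gave 838 for the change with time without IL-4. Leaving out mitochondrial, ribosomal protein and pseudogene transcripts gave 1685, 2552, 452 and 2630 for the IL-21 effects in the same order, 68 and 1043 for the interactions and 554 and 697 for the changes with time. After removal of the trend with GC content and length, 3053 genes were called for IL-21 with IL-4 at 24 h and 87 for the interaction at 6 h.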

Other observations

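No test in this part was chosen to explain a result; the values are given as measured. Libraries of the 24 h group with anti-CD40 and IL-4 differed among themselves in the panel genes. Irf4 was at 58.4, 22.4 and 14.72 TPM in replicates 1, 2 and 3, Fcer2a at 1676, 719.7 and 461.1 TPM and Bcl6 at 5.84, 2.293 and 1.354 TPM. Deviations from the group mean correlated with the GC content of genes at 0.36, -0.169 and -0.319 and with their length at 0.321, -0.251 and -0.222 in the same order. In naive cells the correlation with GC content was 0.306 in replicate 1 and -0.339 in replicate 3.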
